A study of Homo sapiens with 32 samples.

How the data were processed

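RD, a cultured cell line derived from a human embryonal rhabdomyosarcoma (a tumour of cells resembling immature skeletal muscle), was profiled by RNA sequencing in 32 libraries. The labels give 4 siRNAs, 2 control siRNAs (control si4 and control si5) and 2 siRNAs against ASAP1 (ASAP1 si4 and ASAP1 si17), each combined with DMSO, the vehicle, or with trametinib, an inhibitor of the kinases MEK1 and MEK2. Treatment began 48 hours after transfection and lasted 2 or 3 days, and the labels do not assign either duration to a library. Each siRNA with each treatment has 4 libraries, of which 2 carry the set letter A and 2 the set letter B. The labels do not say whether these libraries come from separate cultures, so every p-value below measures the spread between these samples alone.

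The deposited table gives FPKM (fragments normalised to the length of the gene and to the size of the library) for 18011 genes in every library, and this unit is stated in the name the authors gave the table. According to the submitters' processing notes, reads were aligned with STAR 2.5.1 to hg19 and quantified with Partek software. The settings of the quantification, any trimming of reads and the gene annotation release are not given in the sources used here. The values were checked for what lies behind them: FPKM multiplied by the distance between the listed start and stop of a gene falls on multiples of 1 step in each library. Among values worth under 50 reads, 82.3% to 83.6% per library were whole multiples within a tolerance of 0.02. The length in the FPKM is therefore the whole span of the gene with its introns, and a long gene has a low FPKM at a given number of reads. Reads on the listed genes, recovered from these steps, came to 4997184 to 8543399 per library, and these were used only for an alternative fit chosen after seeing the data.

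Differences were computed on log2(FPKM + 1) in R 4.3.3 with limma 3.58.1, using 1 fit with 4 group means and an empirical Bayes spread that follows the mean level. Genes with an FPKM of at least 1 in at least 8 libraries were tested, which left 6586 genes. Of the genes with at least 10 reads in 8 libraries, 6505 failed that filter, with a median span of 55152 bp against 15097 bp for the tested genes. The pseudocount of 1 makes fold changes of genes with low FPKM smaller than the ratio of their mean levels. P-values were adjusted by the method of Benjamini and Hochberg over the genes tested, with a threshold of 0.05. The level of ASAP1, whose span of introns puts it below the filter, was compared by a two-sided exact permutation test. A separate fit with 8 means compared single siRNAs with each other.

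Genes are named by a rule set before the data were examined. For each comparison of groups it takes the 12 largest increases and the 12 largest decreases among genes past the threshold with a mean FPKM of at least 1 and the same sign in all 4 combinations of siRNA and set letter. For the interaction, which asks whether the response to trametinib differed between ASAP1 and control siRNA, it takes the 6 largest of each sign. Among the genes taken, 1 is not reported here. Added to these are up to 2 called members per direction of each gene list, and a short set named in advance, such as ASAP1, MYOD1, MYOG, DUSP6 and MKI67. The 30 gene lists, with 771 entries, were also set before the data were examined. Lists with at least 3 tested members, 26 in all, were compared with the other tested genes by camera in limma with a preset correlation between genes of 0.01, and again with an estimated correlation. The list of mitochondrially encoded genes could not be tested because 0 of its 13 members are in the table.

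The alternatives were a pseudocount of 0.1, no filter, a filter at an FPKM of 5, quantile normalization, scaling by median ratios, the set letter as a covariate, 8 means in place of 4, the siRNA as a random block, each siRNA left out, each set letter alone, and a robust empirical Bayes step. Fits on recovered reads with voom over 13069 genes, the requirement of a change in every pair of siRNAs, and single libraries left out of the siRNA comparisons were chosen after seeing the data. The fit was tested on simulated data: of genes shifted by a log2 difference of 0.5 between ASAP1 and control groups in DMSO, 76% were recovered, with 5 false calls among 6586 genes. The simulation holds no differences between siRNAs, and in the data groupings that mix ASAP1 and control siRNAs called 2147 and 1325 genes in DMSO, so it does not give the false calls of the ASAP1 comparisons. For a comparison between groups of libraries, other splits of the same libraries were counted, and so were groupings that keep the libraries of each siRNA together and splits of the treatments within each siRNA. Values per library were screened for outlying libraries with Dixon's ratio. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 was used for the depth of the libraries and for drawing.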

Results

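The data comprised 4 groups of 8 libraries: control siRNA with DMSO, ASAP1 siRNA with DMSO, control siRNA with trametinib and ASAP1 siRNA with trametinib. Each group joined 4 libraries from each of its 2 siRNAs. Reads on listed genes numbered 4997184 to 8135925 per library in ASAP1 siRNA with DMSO and 5517064 to 7202041 in ASAP1 siRNA with trametinib. The ranges were 6174169 to 8543399 for control siRNA with DMSO and 5087908 to 7094844 for control siRNA with trametinib. Between 5529 and 6177 genes per library reached an FPKM of 1. Log2 differences are given with their SE, and FPKM as mean ± SD over the 8 libraries of a group.

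ASAP1, which encodes a GTPase-activating protein for ARF GTPases with roles in adhesion and the actin cytoskeleton, fell in both treatments. The gene lies on the minus strand of chromosome 8 in hg19, from 131064351 to 131455907. In DMSO its level was 0.64 ± 0.0475 FPKM with control siRNA and 0.0798 ± 0.0461 FPKM with ASAP1 siRNA (SD, n = 8), or 12.5% of control. In trametinib the levels were 0.644 ± 0.122 and 0.0901 ± 0.0537 FPKM, or 14% of control. The low FPKM reflects the long span of the gene, since the mean number of reads was 2277 per control library and 266 per ASAP1 siRNA library in DMSO. ASAP1 si17 left 6.03% and ASAP1 si4 left 18.9% of the control level in DMSO, and 6.52% and 21.4% in trametinib. Every ASAP1 siRNA library lay below every control library of its treatment, with the highest at 0.144 FPKM against the lowest control at 0.567 in DMSO. The two-sided exact permutation p was 0.000155 in each treatment, the smallest that 12870 splits can give. For a single ASAP1 siRNA against the controls the exact p was 0.00202, the smallest that 495 splits can give. These splits part libraries of the same siRNA, and the 3 groupings that keep them together are too few for a small p. ASAP2 and ASAP3 of the same family stayed below an FPKM of 1 in every library and were not tested. In trametinib ASAP2 stood at 0.555 and 0.296 FPKM with ASAP1 si4 and si17, against 0.365 and 0.337 with control si4 and si5. ASAP3 stood at 0.885 and 0.677 against 0.66 and 0.816.

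**Figure D1:**
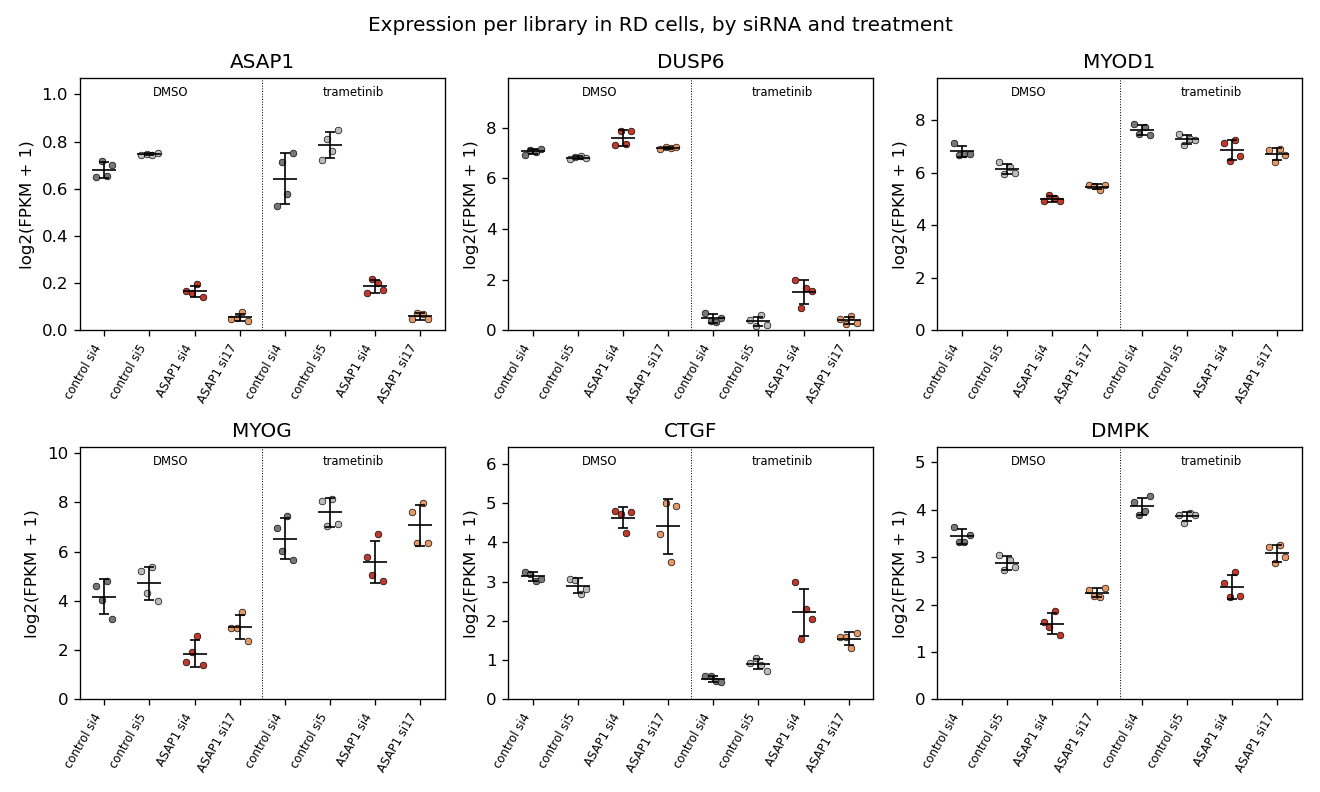
Level of 6 genes in each library as log2(FPKM + 1), grouped by siRNA (horizontal axis) within DMSO and trametinib. Points are libraries, 4 per siRNA and treatment, and bars give the mean and SD. ASAP1 lies lower with both ASAP1 siRNAs, and DUSP6 falls from 122 ± 12.8 to 0.335 ± 0.167 FPKM (mean ± SD of 8 libraries) with trametinib under control siRNA.

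In DMSO, ASAP1 siRNA against control siRNA asks what lowering ASAP1 does to the transcriptome of RD cells. Of the tested muscle contractile genes 19 of 36 fell. Of the myogenic factors and cofactors 9 of 18 fell, among them the transcription factor genes MYOG and MYOD1. CTGF and CYR61, which encode secreted proteins induced by YAP and TGF-beta signalling, rose. Neither muscle list passed with an estimated correlation between genes (adjusted p = 0.346 and 0.161). MYOG (chromosome 1, 203052257 to 203055167) changed from 23 ± 11 FPKM with control siRNA to 4.89 ± 3.02 with ASAP1 siRNA (SD, n = 8), a log2 difference of -2.05 ± 0.42 (adjusted p = 0.00072). MYOD1 (chromosome 11, 17741110 to 17743679) went from 90.7 ± 26.3 to 37.2 ± 6.85 FPKM, a log2 difference of -1.23 ± 0.15 (adjusted p = 1.27e-06). CTGF rose from 7.14 ± 1.02 to 23.1 ± 7.1 FPKM, or 1.51 ± 0.19 on the log2 scale (adjusted p = 1.98e-06). These p-values take the 8 libraries of a group as replicates, and with the siRNA as a random block MYOG, MYOD1, CTGF and CYR61 did not pass (adjusted p = 0.451, 0.16, 0.221 and 0.212). In all, 1400 of 6586 genes passed the threshold, 891 higher and 509 lower, of which 26 and 24 differed by a log2 value of at least 1.

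Among muscle contractile and terminal differentiation genes, 0 of 36 tested members rose, 19 fell and 17 did not pass the test, with 0 up and 23 down adjusted over the list alone (camera adjusted p = 3.84e-11, and adjusted p = 0.346 with an estimated correlation). The cardiac actin gene ACTC1 and the fast myosin light chain gene MYLPF fell, with log2 differences of -1.67 ± 0.26 and -1.37 ± 0.47. Other large decreases were in DES, which encodes desmin, SYNPO2L, DMPK, the kinase gene expanded in myotonic dystrophy, MSTN, which encodes the muscle growth inhibitor myostatin, and MYMX, which encodes a peptide needed for myoblast fusion, at -1.35, -1.29, -1.24, -1.24 and -1.22. MYH3, MYH8 and CKM, markers of late differentiation, did not pass the test, at -0.22, -0.15 and -0.20. At their low levels the added 1 makes such differences small, as for MYH8, at 0.142 ± 0.0667 FPKM with control siRNA and 0.0294 ± 0.0254 with ASAP1 siRNA. Myogenic regulatory factors and cofactors had 9 decreases and 1 increase among 18 tested, in HEY1 (0.45), with 8 not past the test and 9 down and 2 up adjusted over the list alone (camera adjusted p = 0.00233, and adjusted p = 0.161 with an estimated correlation). The list joins activators of the muscle programme, such as MYOD1 and MYOG, with repressors, such as HEY1. Its counts alone therefore give no direction of differentiation. UBE2M, which encodes a NEDD8-conjugating enzyme, its pseudogene UBE2MP1 and the ribosomal gene RPS26 were also among the largest decreases (-1.21, -1.2 and -1.18), and reads can be shared between UBE2M and UBE2MP1.

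Of the increases, CYR61, the transcription factor gene KLF4, the sphingosine kinase gene SPHK1, the thrombomodulin gene THBD, the cytokine gene LIF and PHLDA2 rose by 1.46, 1.41, 1.28, 1.27, 1.22 and 1.3. ADM2, VGF and NPTX1, which encode secreted peptides and proteins, and the interferon-induced IFIT3 rose by 1.29, 1.27, 1.19 and 1.24. Among YAP-TEAD target genes, 6 of the 12 tested rose, 0 fell and 6 did not pass (7 up and 0 down adjusted over the list alone) (camera adjusted p = 0.000423, and adjusted p = 0.0835 with an estimated correlation). In the TGF-beta response list, which shares CTGF with another list, 5 of the 10 tested rose, 0 fell and 5 did not pass (5 up and 0 down adjusted over the list alone) (camera adjusted p = 0.00154, and adjusted p = 0.124 with an estimated correlation). Of the MEK-ERK output genes, transcripts that follow ERK activity, 12 of the 25 tested rose, 0 fell and 13 did not pass (14 up and 0 down adjusted over the list alone) (camera adjusted p = 4.16e-07, and adjusted p = 0.0835 with an estimated correlation). In DMSO, DUSP6 stood at 142 to 231 FPKM in the ASAP1 siRNA libraries and at 108 to 140 in the control libraries. DUSP6, SPRY4 and ETV5 of that list did not pass in the fit, whose spread is shared with the trametinib groups, at 0.46 ± 0.19, 0.0044 ± 0.15 and -0.12 ± 0.056. For type I interferon response genes, 8 of the 19 tested rose, 1 fell and 10 did not pass (9 up and 1 down adjusted over the list alone) (camera adjusted p = 0.00346, and adjusted p = 0.475 with an estimated correlation).

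Metabolic and stress genes also differed. In the integrated stress response list, targets of the transcription factor ATF4, 10 of the 20 tested rose, 0 fell and 10 did not pass (15 up and 0 down adjusted over the list alone) (camera adjusted p = 3.2e-05, and adjusted p = 0.475 with an estimated correlation), led by CHAC1 (1.26) and TRIB3 (1.12). Cholesterol biosynthesis genes showed the opposite sign: of 20 tested, 0 rose, 6 fell and 14 did not pass (0 and 9 adjusted over the list alone), including SREBF2 (-0.66) and MSMO1 (-0.60; camera adjusted p = 3.03e-05, and adjusted p = 0.475 with an estimated correlation). By single siRNA, 20 of 20 integrated stress response genes rose with ASAP1 si4, whereas 4 rose and 3 fell with ASAP1 si17. Cholesterol genes had 0 higher and 19 lower with ASAP1 si4, and 5 higher and 2 lower with ASAP1 si17. Of the cytosolic ribosomal protein genes, read as a check of RNA quality, 0 of the 38 tested rose, 3 fell and 35 did not pass (0 up and 1 down adjusted over the list alone) (camera adjusted p = 1.37e-05, and adjusted p = 0.59 with an estimated correlation). MKI67, a marker of cycling cells, CCND1, MYC and CDKN1A did not pass the test, at -0.40, -0.12, 0.23 and -0.18. For CDKN1A this average joins opposite signs. Its mean was 29.5 FPKM with ASAP1 si4 and 5.44 with ASAP1 si17, against 16.5 and 13.8 with control si4 and si5. MKI67 stood at 4.22 and 12.7 FPKM with ASAP1 si4 and si17, and at 6.57 and 14.9 with control si4 and si5. Markers of other cell types were few among tested genes: KRT18 (0.66) and CLDN4 (0.51) of the epithelial list and CD68 (0.62) of the leukocyte list rose, and LUM (-0.50) of the fibroblast list fell. The share of calls that were increases was 63.6%, against 49.1% after quantile normalization. With the siRNA as a random block, 10 genes passed. Of these, 8 were higher (VGF, ANGPT2, SH2B3, LRRC8D, TRIB1, PPP2R1B, ITPRIP and ANKFY1) and 2 lower (DMPK and PDLIM4). This block counts the spread between siRNAs of 1 kind through 1 correlation shared by all genes (0.653). The spread between siRNAs was therefore not estimated for each gene, and differences between single siRNAs stay open for these 10 genes.

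In trametinib the same comparison asks what lowering ASAP1 does while MEK is inhibited. CYR61, CTGF and the receptor gene TNFRSF12A rose, while ERBB3, a receptor tyrosine kinase gene, and 13 of 36 tested muscle contractile genes fell, a list that did not pass with an estimated correlation (adjusted p = 0.511). TNFRSF12A went from 3.99 ± 1.47 FPKM with control siRNA to 14.4 ± 5.84 with ASAP1 siRNA (SD, n = 8; log2 difference 1.58 ± 0.22, adjusted p = 7.34e-06). ERBB3 went from 13.1 ± 4.36 to 3.26 ± 1.87 FPKM (-1.77 ± 0.21, adjusted p = 5.52e-07). With the siRNA as a random block, TNFRSF12A, ERBB3, CYR61 and CTGF did not pass (adjusted p = 0.0935, 0.155, 0.209 and 0.356). In all, 1733 genes passed, 1077 higher and 656 lower, with 13 and 18 at a log2 difference of at least 1. Muscle contractile genes again had more decreases: of 36 tested, 0 rose, 13 fell and 23 did not pass (0 and 24 adjusted over the list alone) (camera adjusted p = 8.39e-09, and adjusted p = 0.511 with an estimated correlation). The perinatal myosin gene MYH8, MYBPH, TNNT2, which encodes a troponin, and MYH3 differed by -1.58, -1.4, -1.13 and -1.09, whereas CKM at -0.78 did not pass. MYOD1 fell from 175 ± 31.6 to 112 ± 24.3 FPKM (-0.65 ± 0.15), while MYOG at -0.73 ± 0.42 did not pass. Over both treatments, libraries with the same siRNA, treatment and set letter differed in MYOG by a median ratio of 2.21, which counts as spread here. Across the myogenic regulatory factors, 1 of the 18 tested rose, 2 fell and 15 did not pass (1 up and 2 down adjusted over the list alone) (camera adjusted p = 0.222, and adjusted p = 0.511 with an estimated correlation). DMPK, the hemojuvelin gene HFE2, the tight junction gene CLDN5, the transcription factor gene FOXO4, the long noncoding ZFAS1, RPS26, UBE2M and UBE2MP1 differed by -1.24, -1.33, -1.19, -1.18, -1.26, -1.39, -1.24 and -1.11.

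Increases in trametinib included CYR61 (1.41 ± 0.23), CTGF (1.17 ± 0.19), the transcription factor gene KLF2 (1.26 ± 0.24), the urokinase gene PLAU (1.17 ± 0.32) and IDH1 (1.23 ± 0.18), which encodes the cytosolic isocitrate dehydrogenase. For CTGF, replicate 1 of ASAP1 siRNA with trametinib stood at 6.95 FPKM against 1.46 to 3.92 in the other libraries of its group. CHAC1, ADM2, CEBPG, CEBPB, PEA15 and CTXN1 rose by 1.45, 1.34, 1.1, 1.0, 1.06 and 1.06. In the integrated stress response list, 10 of the 20 tested rose, 0 fell and 10 did not pass (13 up and 0 down adjusted over the list alone) (camera adjusted p = 0.000726, and adjusted p = 0.511 with an estimated correlation). YAP-TEAD target genes had 5 increases: of 12 tested, 5 rose, 0 fell and 7 did not pass (5 and 0 adjusted over the list alone) (camera adjusted p = 0.0251, and adjusted p = 0.471 with an estimated correlation). For TGF-beta response genes, 4 of the 10 tested rose, 0 fell and 6 did not pass (4 up and 0 down adjusted over the list alone) (camera adjusted p = 0.0127, and adjusted p = 0.471 with an estimated correlation). MEK-ERK output genes as a list did not pass: 5 of the 25 tested rose, 0 fell and 20 did not pass (5 up and 0 down adjusted over the list alone) (camera adjusted p = 0.0914, and adjusted p = 0.511 with an estimated correlation). Of the cytosolic ribosomal protein genes, 0 of the 38 tested rose, 15 fell and 23 did not pass (0 up and 18 down adjusted over the list alone) (camera adjusted p = 8.39e-09, and adjusted p = 0.511 with an estimated correlation). Among cholesterol biosynthesis genes, 0 of the 20 tested rose, 3 fell and 17 did not pass (0 up and 3 down adjusted over the list alone) (camera adjusted p = 0.000409, and adjusted p = 0.511 with an estimated correlation). By single siRNA, integrated stress response genes had 19 higher and 0 lower with ASAP1 si4, and 4 higher and 4 lower with ASAP1 si17. Cholesterol genes had 0 higher and 19 lower with ASAP1 si4, and 7 higher and 4 lower with ASAP1 si17. Increases made up 62.1% of calls, against 48.7% after quantile normalization. With the siRNA as a random block, 7 genes passed, 6 higher (KLHL15, CEBPG, ANKFY1, HOXB9, IDH1 and FAM168B) and 1 lower (DMPK). The correlation shared by all genes limits these calls as it does in DMSO.

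Across genes, the difference between ASAP1 and control siRNA in DMSO followed that in trametinib, with r = 0.815 and rho = 0.817 over 6586 genes, which are not independent replicates and share the same siRNAs. Of the called genes, 613 were higher in both treatments and 328 lower in both, against 146 and 50.7 by chance, and 2 had opposite signs.

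Single siRNAs show how much of this belongs to 1 sequence. Between the control siRNAs, si5 against si4, 2563 genes differed in DMSO (1508 higher and 1055 lower, or 1241 and 1337 after quantile normalization) and 2469 in trametinib, although neither targets ASAP1. Between the ASAP1 siRNAs, si17 against si4, 3868 genes differed in DMSO and 4172 in trametinib. Against both control siRNAs, ASAP1 si4 had 4030 calls in DMSO and 4198 in trametinib, and ASAP1 si17 had 2420 and 2718. In DMSO, 651 genes were higher with both ASAP1 siRNAs, 292 lower with both and 662 had opposite signs, and in trametinib the counts were 745, 301 and 782. After quantile normalization 450 were higher and 444 lower with both in DMSO, and 551 and 467 in trametinib, so the balance of increases depended on the scaling. Both differences share the control libraries, which adds to the genes of equal sign, and independent lists would give 492 and 242 in DMSO and 592 and 269 in trametinib. With ASAP1 si4 set against control si4 and ASAP1 si17 against control si5, 380 were higher and 203 lower with both in DMSO, where chance gives 330 and 187, and 456 and 228 in trametinib, where chance gives 398 and 210. With the control siRNAs exchanged, 455 and 222 in DMSO and 477 and 250 in trametinib lay below the 502 and 283, and 558 and 312, that chance gives. Because of the shared controls, the correlation of both differences across genes, r = 0.219 in DMSO and 0.169 in trametinib, was set against 100 simulated unchanged groups, which gave 0.333 and 0.332. The covariance was 0.0231 in DMSO and 0.0188 in trametinib against 0.00295 and 0.00294 in the simulated groups, which hold no difference between siRNAs. The difference between the control siRNAs adds 0.0206 and 0.0192 through the shared control mean, so the excess is not read as a shared effect. With the control siRNAs divided between the ASAP1 siRNAs, r was 0.114 or -0.054 in DMSO and 0.094 or -0.078 in trametinib. A change of the same sign in all 4 pairs of an ASAP1 and a control siRNA was found in 307 genes in DMSO and 344 in trametinib. Of these, 98 were higher and 38 lower in both treatments.

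Gene groups differed in how they moved with each ASAP1 siRNA. The median log2 difference of the muscle contractile list in DMSO was -0.58 with ASAP1 si4 and -0.49 with ASAP1 si17, with 20 and 16 of 36 members lower. Control si5 against control si4 gave a median of -0.41 for the same list in DMSO, with 6 members lower, and -0.083 in trametinib. YAP-TEAD target genes had medians of 0.73 and 0.37 with ASAP1 si4 and si17, and -0.053 between the controls. TGF-beta response genes had 0.40, 0.60 and -0.13. The integrated stress response list stood at 1.22 with ASAP1 si4, where 20 of 20 members rose, and at 0.029 with ASAP1 si17, where 4 rose and 3 fell. Cholesterol biosynthesis genes had medians of -0.79 and 0.043, and cytosolic ribosomal protein genes -0.36 and -0.025. In trametinib the medians with ASAP1 si4 and si17 were 1.24 and 0.083 for the integrated stress response, -0.61 and 0.017 for cholesterol biosynthesis and -0.55 and -0.0010 for cytosolic ribosomal protein genes, of which 37 and 2 of 38 fell. Of type I interferon response genes in DMSO, 9 rose and 4 fell with ASAP1 si4, and 15 rose and 1 fell with ASAP1 si17, while control si5 against control si4 had 11 of 19 lower (median -0.38). Against control si4 alone, 4 rose and 6 fell with ASAP1 si4. DNA replication genes moved apart, with 21 of 23 lower with ASAP1 si4 (median -0.72) and 13 of 23 higher with ASAP1 si17 (median 0.30). G2/M and mitosis genes did the same in DMSO, with 28 of 30 lower with ASAP1 si4 and 10 of 30 higher with ASAP1 si17, while control si5 had 27 of 30 higher than control si4.

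**Figure D2:**
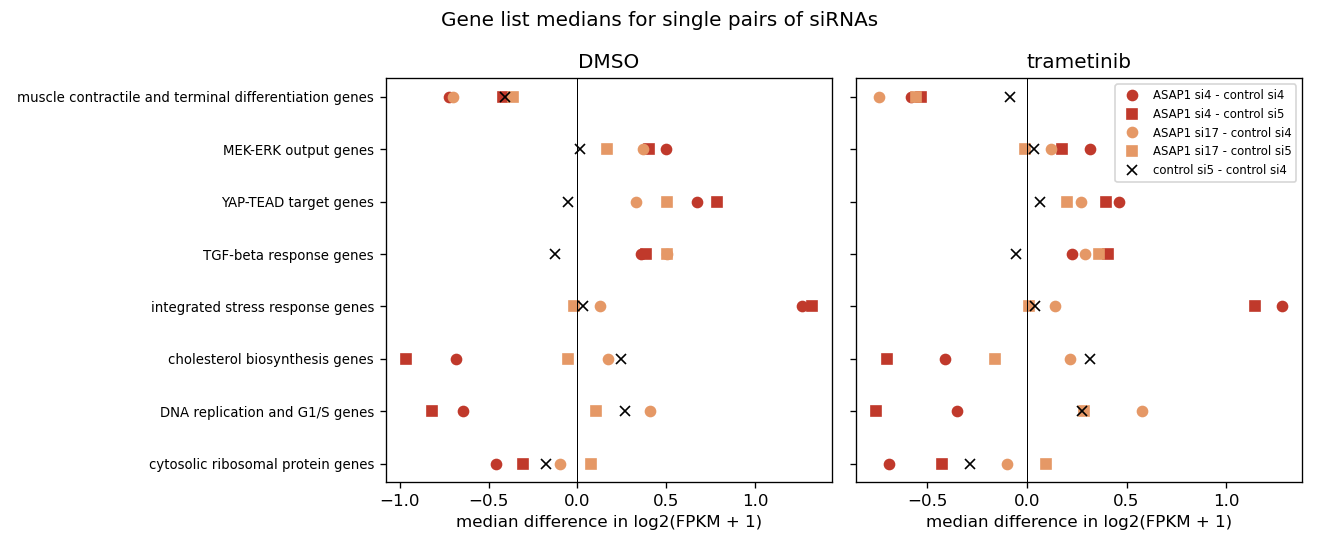
Median difference in log2(FPKM + 1) over the members of 8 gene lists (vertical axis) for each pair of an ASAP1 and a control siRNA and for the pair of control siRNAs, in DMSO and in trametinib. The integrated stress response list stands at 1.26 and 1.32 for ASAP1 si4 in DMSO and near 0 for ASAP1 si17, and the muscle list is below 0 in every pair.

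Trametinib against DMSO with control siRNA asks what MEK inhibition does to RD cells. Of the tested genes that follow ERK activity 23 of 25 fell, 33 of 36 muscle contractile genes rose, and 19 of 23 genes of DNA replication and 30 of 30 of mitosis fell. Only the first of these lists also passed with an estimated correlation between genes. That correlation was estimated from the residuals of the fit with 4 group means, which still hold differences between siRNAs. It was 0.141 for the MEK-ERK output genes, 0.616 for muscle contractile, 0.792 for DNA replication and 0.93 for mitosis genes. Failing that test therefore does not show that a list was unchanged. DUSP6, the ERK phosphatase gene (chromosome 12, minus strand, 89741602 to 89746637), went from 122 ± 12.8 FPKM in DMSO to 0.335 ± 0.167 in trametinib (SD, n = 8), a log2 difference of -6.53 ± 0.19 (adjusted p = 7.06e-23). MYOG went from 23 ± 11 to 154 ± 84.6 FPKM (2.62 ± 0.42, adjusted p = 9.9e-06), and MYH8 from 0.142 ± 0.0667 to 11.5 ± 13.1 FPKM (2.79 ± 0.39, adjusted p = 1.26e-06). In all, 2380 genes passed, 853 higher and 1527 lower, with 82 and 132 at a log2 difference of at least 1. Each siRNA was given both treatments, and with the siRNA as a random block 1300 genes passed higher and 2412 lower. Increases made up 35.8% of calls, against 50.6% after quantile normalization and 48.2% after scaling by median ratios.

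Of the MEK-ERK output genes, 1 of the 25 tested rose, 23 fell and 1 did not pass (1 up and 23 down adjusted over the list alone) (camera adjusted p = 1.89e-24), and this held with an estimated correlation (adjusted p = 0.000134). SPRY4 and SPRY2, feedback inhibitors of receptor signalling, and the immediate early gene EGR1 differed by -3.67 ± 0.15, -3.58 ± 0.11 and -3.53 ± 0.16. CCND1, which encodes cyclin D1, and ETV5 differed by -2.21 and -1.34, while MYC at 0.13 did not pass and TRIB1 rose by 0.50. Other large decreases were in the Wnt antagonist gene DKK1 (-3.97), the BMP antagonist gene NOG (-3.41), the neurotrophin receptor gene NGFR (-3.34), PLAU (-3.11), EMP1 (-3.14), TRIL (-3.83) and VMO1 (-3.53). In control siRNA with DMSO, EGR1 stood at 22.8 FPKM in replicate 6 against at most 13 in the other libraries, and HSPB3, described next, at 2.09 FPKM in replicate 5 against at most 1.11.

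Among muscle contractile and terminal differentiation genes, 33 of the 36 tested rose, 1 fell and 2 did not pass (34 up and 1 down adjusted over the list alone) (camera adjusted p = 2.21e-19, and adjusted p = 0.262 with an estimated correlation), the decrease being in CHRNA1 (-1.38), which encodes an acetylcholine receptor subunit. MYLPF, ACTC1, MYBPH, SYNPO2L and the troponin genes TNNC1 and TNNI1 rose by 2.57, 2.5, 2.21, 2.26, 2.19 and 2.19. MYH3, CKM and MYOD1 rose by 2.04, 1.72 and 0.97. Beyond muscle, the GTPase gene RHOB, the transcription factor gene MYCL, the small heat shock protein gene HSPB3 and the potassium channel gene KCNF1 rose by 2.54, 2.31, 2.24 and 2.21. Myogenic regulatory factors and cofactors, a list of activators and repressors of the muscle programme, moved both ways: 5 of the 18 tested rose, 6 fell and 7 did not pass (5 up and 6 down adjusted over the list alone) (camera adjusted p = 0.607, and adjusted p = 0.761 with an estimated correlation). In the Notch pathway list, 7 of the 12 tested rose, 3 fell and 2 did not pass (7 up and 3 down adjusted over the list alone) (camera adjusted p = 0.000395, and adjusted p = 0.262 with an estimated correlation), with HEYL (1.3) and DLL1 (1.27) up and JAG1 (-0.77) down.

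Every tested G2/M and mitosis gene fell in trametinib with control siRNA, 30 of 30 over all genes and 30 adjusted over the list alone (camera adjusted p = 3.91e-10, and adjusted p = 0.373 with an estimated correlation), and MKI67 differed by -1.8 ± 0.36. For DNA replication and G1/S genes, 0 of the 23 tested rose, 19 fell and 4 did not pass (0 up and 20 down adjusted over the list alone) (camera adjusted p = 1.25e-05, and adjusted p = 0.442 with an estimated correlation), with RRM2, a subunit gene of ribonucleotide reductase, at -1.85. The cyclin-dependent kinase inhibitor genes CDKN1C and CDKN1A rose by 1.76 and 1.49. Of the type I interferon response genes, 0 of the 19 tested rose, 15 fell and 4 did not pass (1 up and 15 down adjusted over the list alone) (camera adjusted p = 6.41e-06, and adjusted p = 0.333 with an estimated correlation), with IFIT3 at -2.47 and IFIT2 at -2.43. Among NF-kB and inflammatory genes, 0 of the 7 tested rose, 6 fell and 1 did not pass (0 up and 6 down adjusted over the list alone) (camera adjusted p = 0.0154, and adjusted p = 0.373 with an estimated correlation). In the TGF-beta response list, 1 of the 10 tested rose, 5 fell and 4 did not pass (1 up and 5 down adjusted over the list alone) (camera adjusted p = 0.0183, and adjusted p = 0.333 with an estimated correlation). CTGF and CYR61 fell, at -2.31 and -1.75, while the YAP-TEAD list as a whole did not pass: 4 of the 12 tested rose, 5 fell and 3 did not pass (4 up and 5 down adjusted over the list alone) (camera adjusted p = 0.757, and adjusted p = 0.89 with an estimated correlation). Of the cytosolic ribosomal protein genes, 29 of the 38 tested rose, 0 fell and 9 did not pass (32 up and 0 down adjusted over the list alone) (camera adjusted p = 1.05e-10, and adjusted p = 0.373 with an estimated correlation). The epithelial keratin gene KRT18 fell by 2.02 and the leukocyte marker CD68 by 0.63 on the log2 scale, and the neural marker TUBB3 rose by 0.82.

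With ASAP1 siRNA, the same question about trametinib gave a similar picture of single genes. DUSP6 went from 171 ± 37.5 to 1.15 ± 1.06 FPKM (SD, n = 8; log2 difference -6.44 ± 0.19, adjusted p = 1.06e-22), and MYOG from 4.89 ± 3.02 to 103 ± 79 FPKM (3.94 ± 0.42, adjusted p = 5.41e-09). Mean DUSP6 in trametinib was 1.98 FPKM with ASAP1 si4 and 0.314 with ASAP1 si17, against 0.389 and 0.282 with control si4 and si5. ACTC1 rose from 15.1 ± 4.07 to 201 ± 85.6 FPKM (3.58 ± 0.26, adjusted p = 1.1e-12). In all, 2519 genes passed, 919 higher and 1600 lower, with 102 and 148 at a log2 difference of at least 1. With the siRNA as a random block, 1450 passed higher and 2482 lower. Increases made up 36.5% of calls, against 51.4% after quantile normalization and 48.1% after scaling by median ratios. Decreases included DKK1 (-4.52), SPRY4 (-3.65), EGR1 (-3.47), SPRY2 (-3.43), PLAU (-3.1), NOG (-2.86), TRIL (-4.05) and VMO1 (-3.59), and the interferon-induced IFIT3 (-3.44) and IFIT2 (-3.31). Increases included RHOB (3.43), KLF2 (3.0), OLFML2A (2.83), SYNPO2L (2.82), MYLPF (2.72), TNNI1 (2.57), the glypican gene GPC1 (2.36), MYL1 (2.24), HSPB3 (2.13), TSPAN33 (2.11) and MYOD1 (1.55). DKK1 stood at 6.16 FPKM in replicate 8 of ASAP1 siRNA with trametinib against at most 3.54 in the other libraries. CKM, MYH3 and MYH8 rose by 1.14, 1.17 and 1.36.

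The gene groups moved as follows in the cells with ASAP1 siRNA. Of the MEK-ERK output genes, 1 of the 25 tested rose, 23 fell and 1 did not pass (1 up and 23 down adjusted over the list alone) (camera adjusted p = 1.21e-27, held at adjusted p = 5.01e-05 with an estimated correlation). For muscle contractile genes, 34 of the 36 tested rose, 1 fell and 1 did not pass (34 up and 1 down adjusted over the list alone) (camera adjusted p = 1.56e-18, and adjusted p = 0.22 with an estimated correlation). For G2/M and mitosis genes, 0 of the 30 tested rose, 29 fell and 1 did not pass (0 up and 30 down adjusted over the list alone) (camera adjusted p = 1.46e-07, and adjusted p = 0.465 with an estimated correlation), and MKI67 stood at -1.63. For DNA replication genes, 0 of the 23 tested rose, 13 fell and 10 did not pass (0 up and 14 down adjusted over the list alone) (camera adjusted p = 0.00358, and adjusted p = 0.623 with an estimated correlation). In the interferon list, 0 of the 19 tested rose, 14 fell and 5 did not pass (0 up and 14 down adjusted over the list alone) (camera adjusted p = 8.38e-08, and adjusted p = 0.22 with an estimated correlation). In the Notch pathway list, 8 of the 12 tested rose, 1 fell and 3 did not pass (8 up and 1 down adjusted over the list alone) (camera adjusted p = 0.000139, and adjusted p = 0.22 with an estimated correlation). Of the glycolysis genes, 0 of the 17 tested rose, 11 fell and 6 did not pass (0 up and 11 down adjusted over the list alone), and the decreases included SLC2A3 (-1.57) and LDHA (-0.91; camera adjusted p = 0.00835, and adjusted p = 0.465 with an estimated correlation). Among cytosolic ribosomal protein genes, 14 of the 38 tested rose, 0 fell and 24 did not pass (17 up and 0 down adjusted over the list alone) (camera adjusted p = 8.61e-07, and adjusted p = 0.479 with an estimated correlation). Across genes, the response with ASAP1 siRNA followed that with control siRNA at r = 0.93 and rho = 0.891 over 6586 genes, which are not independent replicates. Of the called genes, 670 rose in both and 1209 fell in both, against 119 and 371 by chance, and 1 had opposite signs.

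Whether the response to trametinib differed between ASAP1 and control siRNA was tested by the interaction, which 14 of 6586 genes passed, 2 positive and 12 negative, while 355 genes had an unadjusted p under 0.05. Each siRNA was given both treatments, and this fit with 4 group means counts differences between siRNAs as spread. With the siRNA as a random block, 60 genes passed with a positive and 62 with a negative sign. MSTN stayed at 63.9 ± 11.5 and 67 ± 4.96 FPKM in DMSO and trametinib with control siRNA, and rose from 27.8 ± 9.91 to 90 ± 36.1 FPKM with ASAP1 siRNA (SD, n = 8; interaction 1.55 ± 0.29, adjusted p = 0.00782). RHOB rose from 17.2 ± 3.47 to 105 ± 20.1 FPKM with control siRNA and from 15.6 ± 2.23 to 179 ± 31.1 with ASAP1 siRNA (interaction 0.89 ± 0.18, adjusted p = 0.0125). FURIN, which encodes a protease that matures growth factor precursors, rose from 6.2 ± 1.06 to 10.6 ± 1.01 FPKM with control siRNA and stood at 7.98 ± 0.863 and 6.77 ± 1.11 with ASAP1 siRNA (interaction -0.91 ± 0.13, adjusted p = 9.77e-05). VGF (-1.27 ± 0.11), IL7R (-0.99 ± 0.22), RSAD2 (-0.90 ± 0.20), ANGPT2 (-0.74 ± 0.088) and FAM84B (-0.70 ± 0.13) also passed, and each was higher with ASAP1 siRNA than with control siRNA in DMSO and fell with trametinib under either kind of siRNA. For VGF the mean went from 0.993 ± 0.267 to 0.118 ± 0.0861 FPKM with control siRNA and from 3.8 ± 0.732 to 0.11 ± 0.0557 with ASAP1 siRNA. DUSP6 (0.088), MYOG (1.32), MYOD1 (0.58), CCND1 (0.70) and MKI67 (0.18) did not pass the test of the interaction in the fit with 4 group means.

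Of the lists, the MEK-ERK output genes had a negative interaction, with 3 of 25 past the test of the interaction, all negative, 22 not past it, and 6 negative adjusted over the list alone (camera adjusted p = 2.56e-07, and adjusted p = 0.128 with an estimated correlation). These 3 genes, VGF, SPRED3 and ETV4, had means of 0.0216 to 0.137 FPKM in trametinib with either kind of siRNA. On the log2(FPKM + 1) scale a gene brought this near to 0 shows a larger decrease the higher it stood in DMSO. The list was not tested on recovered reads, so its sign is not read as a stronger response to trametinib. For type I interferon response genes, 1 of 19 passed with a negative sign, and 2 adjusted over the list alone (camera adjusted p = 0.000773, and adjusted p = 0.716 with an estimated correlation). For muscle contractile genes, 0 of 36 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.508, and adjusted p = 0.947 with an estimated correlation). On recovered reads, an alternative chosen after seeing the data, 17 of 13069 genes passed, 12 positive and 5 negative, and of the 14 genes here only MSTN, RHOB, FURIN and TGFB3 passed. The filter at an FPKM of 5 left 3 genes past the threshold. The prevalence of negative signs therefore depended on the fit, with 60 positive and 62 negative when the siRNA was a random block and 138 and 135 with 8 means.

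**Figure D3:**
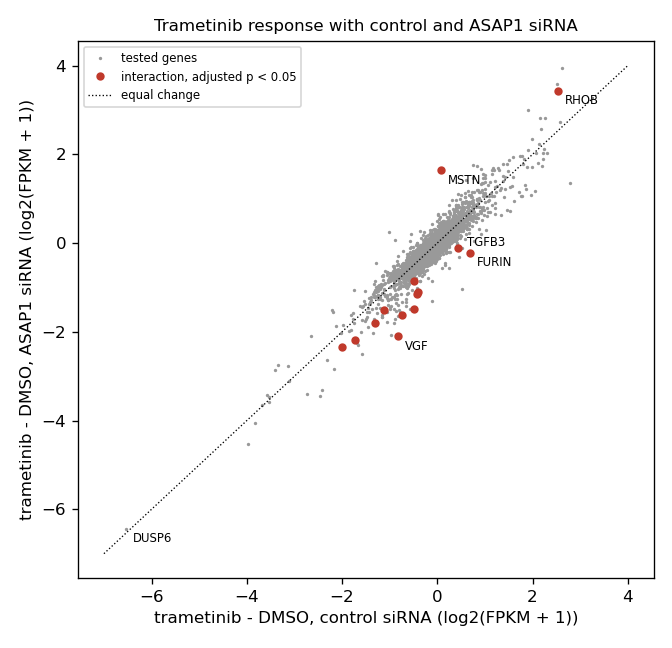
Difference between trametinib and DMSO in log2(FPKM + 1) with control siRNA (horizontal axis) and with ASAP1 siRNA (vertical axis), 1 point per tested gene. Larger points are the 14 genes past the threshold for the interaction, and the dotted line marks equal change. MSTN lies at 0.085 with control siRNA and 1.64 with ASAP1 siRNA.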

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

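The test that set the interaction against recovered reads was chosen after the result was seen. Its first form counted only the calls lost on reads, by which the floor described below accounted for the negative signs, and it was changed after that outcome was seen, to compare the sizes as well and to take genes by their level.

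Among 316 groups of 8 libraries, tested over 79 values, 7 held a library apart from the rest. Chance gives about 15.8 if the 8 libraries vary as 1 normal population. Each group joins 2 siRNAs, which can mask an outlying library, so a count below 15.8 does not show that the others hold none. CTGF stood at 6.95 FPKM in replicate 1 of ASAP1 siRNA with trametinib (the others at 1.46 to 3.92). KLF4 stood at 2.07 FPKM in replicate 7 of ASAP1 siRNA with trametinib (0.704 to 1.24). MYBPH stood at 1.62 FPKM in replicate 6 of ASAP1 siRNA with DMSO (0.0989 to 0.646). HSPB3 stood at 2.09 FPKM in replicate 5 of control siRNA with DMSO (0.319 to 1.11). DKK1 stood at 6.16 FPKM in replicate 8 of ASAP1 siRNA with trametinib (1.3 to 3.54). EGR1 stood at 22.8 FPKM in replicate 6 of control siRNA with DMSO (6.8 to 13). NGFR stood at 1.61 FPKM in replicate 6 of ASAP1 siRNA with trametinib (0.413 to 0.742).

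The fit with 4 group means counts differences between siRNAs as spread. With the siRNA as a random block, 60 genes were positive and 62 negative for the interaction. In the fit with 4 group means, the response to trametinib differed between ASAP1 and control siRNA for 14 genes by the interaction term. With a positive sign these were MSTN (1.55) and RHOB (0.89) on the log2 scale. With a negative sign they were VGF (-1.27), IL7R (-0.99), FURIN (-0.91), RSAD2 (-0.90), ANGPT2 (-0.74), FAM84B (-0.70), TGFB3 (-0.55), SH2B3 (-0.49), SPRED3 (-0.45), GYPC (-0.39), TNFRSF8 (-0.37) and ETV4 (-0.35).

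A candidate explanation for the negative signs is the floor of the log2(FPKM + 1) scale, since a gene that trametinib brings near 0 shows a larger difference on that scale the higher it stood in DMSO. For FURIN and TGFB3 the floor is argued against: their means under trametinib were at least 1 FPKM in both groups, as 10.6 and 6.77 for FURIN and 2.55 and 1.79 for TGFB3, and 2 of 2 kept the call on recovered reads, to which no 1 is added on the FPKM scale (-1.03 and -0.82). Of the 10 negative genes with a mean below 1 FPKM under trametinib, 0 kept the call on reads, and the size was smaller there for 4, as for ETV4 (-0.35 ± 0.051 to -0.044 ± 0.60), and larger for 6, as for VGF (-1.27 ± 0.11 to -1.92 ± 0.51), where the call ended with the wider error, so the floor stays open for these 10. A different response of cells with less ASAP1 stays open for MSTN, RHOB, FURIN and TGFB3, as do differences between single siRNAs.

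Of the gene lists, 8 passed the camera test for the interaction and 0 with an estimated correlation. Lists were not tested on recovered reads, so the floor stays open for the MEK-ERK output genes. Adjusted p was 2.56e-07 for MEK-ERK output genes (median interaction -0.15), 0.000773 for type I interferon response genes (-0.13) and 0.00598 for NF-kB and inflammatory genes (-0.19), all lower. It was 0.00598 for oxidative phosphorylation genes (-0.057), 0.00652 for glycolysis genes (-0.11) and 0.0238 for cytosolic ribosomal protein genes (-0.089), all lower, the last at 0.669 after quantile normalization. For myogenic regulatory factors (0.12) it was 0.00598 and for DNA replication and G1/S genes (0.18) it was 0.00672, both higher.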

How the results depend on the processing

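The fits on recovered reads, the requirement of all 4 siRNA pairs and the single libraries left out were chosen after the data were seen. The counts of genes in the group comparisons were computed under each alternative set before the data were seen and on recovered reads. Counts between siRNAs and the ASAP1 level were computed under the pseudocount, the filters, the scalings and the set letter as a covariate, and not under the other alternatives, apart from single libraries left out for the counts between siRNAs. Counts that moved by more than 1.5 times are given here, and causes were not tested. The ASAP1 level has no value under the filter at an FPKM of 5. With the set letter as a covariate, a check of whether the letters pair libraries, genes called numbered 1346 for ASAP1 siRNA in DMSO, 1682 for ASAP1 siRNA in trametinib, 2348 for trametinib with control siRNA, 2496 for trametinib with ASAP1 siRNA and 13 for the interaction. The deviation of the letters correlated at 0.0958 to 0.469 across genes between groups, and with 2 letters only this does not pair the libraries. Leaving out a single library moved no siRNA count by more than 1.5 times, for example 2082 to 2637 for control si5 against control si4 in DMSO.

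Without a filter, genes called numbered 2396 for ASAP1 siRNA in DMSO, 2881 for ASAP1 siRNA in trametinib, 4704 for trametinib with control siRNA, 4923 for trametinib with ASAP1 siRNA and 41 for the interaction. Genes called between siRNAs numbered 4428 for control si5 against control si4 in DMSO, 6995 for ASAP1 si17 against ASAP1 si4 in DMSO, 7087 for ASAP1 si4 against both control siRNAs in DMSO, 4340 for ASAP1 si17 against both control siRNAs in DMSO and 3935 for control si5 against control si4 in trametinib. Genes called between siRNAs numbered 7513 for ASAP1 si17 against ASAP1 si4 in trametinib, 7507 for ASAP1 si4 against both control siRNAs in trametinib and 4996 for ASAP1 si17 against both control siRNAs in trametinib. Shared genes numbered 1056 for higher in DMSO, 495 for lower in DMSO, 1236 for higher in trametinib and 492 for lower in trametinib. With the filter at an FPKM of 5, genes called numbered 524 for ASAP1 siRNA in DMSO, 672 for ASAP1 siRNA in trametinib, 887 for trametinib with control siRNA, 938 for trametinib with ASAP1 siRNA and 3 for the interaction. Genes called between siRNAs numbered 853 for control si5 against control si4 in DMSO, 1260 for ASAP1 si17 against ASAP1 si4 in DMSO, 1376 for ASAP1 si4 against both control siRNAs in DMSO, 817 for ASAP1 si17 against both control siRNAs in DMSO and 875 for control si5 against control si4 in trametinib. Genes called between siRNAs numbered 1396 for ASAP1 si17 against ASAP1 si4 in trametinib, 1455 for ASAP1 si4 against both control siRNAs in trametinib and 896 for ASAP1 si17 against both control siRNAs in trametinib. Shared genes numbered 236 for higher in DMSO, 132 for lower in DMSO, 243 for higher in trametinib and 134 for lower in trametinib. Gene lists called numbered 4 for the interaction. Of the largest changes, those still called were 3 for the interaction. These filters change how many genes are tested. With a pseudocount of 0.1, genes called numbered 6 for the interaction. The largest changes that kept their call were 5 for the interaction. After quantile normalization, shared genes numbered 444 for lower in DMSO and 467 for lower in trametinib.

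With 8 means, which take differences between siRNAs out of the spread, genes called numbered 3273 for ASAP1 siRNA in DMSO, 3472 for ASAP1 siRNA in trametinib, 3921 for trametinib with control siRNA, 4089 for trametinib with ASAP1 siRNA and 273 for the interaction. Gene lists called numbered 5 for ASAP1 siRNA in trametinib. With the siRNA as a random block, which puts them into the error of the ASAP1 comparison, genes called numbered 10 for ASAP1 siRNA in DMSO, 7 for ASAP1 siRNA in trametinib, 3712 for trametinib with control siRNA, 3932 for trametinib with ASAP1 siRNA and 122 for the interaction. The largest changes that kept their call were 2 for ASAP1 siRNA in DMSO and 3 for ASAP1 siRNA in trametinib. Without ASAP1 si17, genes called numbered 3246 for ASAP1 siRNA in DMSO, 3466 for ASAP1 siRNA in trametinib and 209 for the interaction. Without control si4, genes called numbered 813 for ASAP1 siRNA in DMSO, 1112 for ASAP1 siRNA in trametinib and 1429 for trametinib with control siRNA. Of the largest changes, those still called were 15 for ASAP1 siRNA in trametinib. Without control si5, genes called numbered 1389 for trametinib with control siRNA and 22 for the interaction. The largest changes that kept their call were 15 for ASAP1 siRNA in trametinib and 4 for the interaction.

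In set A alone, genes called numbered 138 for ASAP1 siRNA in DMSO, 144 for ASAP1 siRNA in trametinib, 886 for trametinib with control siRNA, 1078 for trametinib with ASAP1 siRNA and 1 for the interaction. Largest changes still called were 12 for ASAP1 siRNA in DMSO, 9 for ASAP1 siRNA in trametinib and 1 for the interaction. In set B alone, genes called numbered 59 for ASAP1 siRNA in DMSO, 70 for ASAP1 siRNA in trametinib, 829 for trametinib with control siRNA, 945 for trametinib with ASAP1 siRNA and 1 for the interaction. Of the largest changes, those still called were 7 for ASAP1 siRNA in DMSO, 5 for ASAP1 siRNA in trametinib and 1 for the interaction. Each set has 4 libraries per group. With an estimated correlation in camera, gene lists called numbered 0 for ASAP1 siRNA in DMSO, 0 for ASAP1 siRNA in trametinib, 1 for trametinib with control siRNA, 1 for trametinib with ASAP1 siRNA and 0 for the interaction. With voom on recovered reads, genes called numbered 2573 for ASAP1 siRNA in DMSO, 3115 for ASAP1 siRNA in trametinib, 4489 for trametinib with control siRNA and 4691 for trametinib with ASAP1 siRNA. Largest changes still called were 3 for the interaction. With a change required in 4 of 4 siRNA pairs, genes called numbered 307 for ASAP1 siRNA in DMSO and 344 for ASAP1 siRNA in trametinib.

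Among single results, 8 reversed, and the cause was not tested. Without ASAP1 si4, CXCL3 in DMSO stood at -0.045, and in trametinib EEF1A1 at 0.0024, RPL7 at 0.0082 and DUSP6 at -0.020 on the log2 scale. Without control si5, SPRY4 in DMSO stood at -0.51. Without ASAP1 si17, CDKN1A stood at 0.93 in DMSO and 0.78 in trametinib. The muscle contractile list for the interaction took the other direction without a filter (adjusted p = 0.00962). Results for named genes were counted as a gene in 1 comparison. Of these, 148 lost the call with the siRNA as a random block, where 244 kept their status. On recovered reads 15 lost the call, and 1 lost it with the robust step. Of list results, 51 lost the call with an estimated correlation. Depth was 4997184 to 8543399 reads on listed genes per library.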

Other observations

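The tests of other pairings of the siRNAs and of the muscle list for single siRNAs, the groupings that keep the libraries of an siRNA together and the splits within each siRNA were chosen after the results were seen, whereas the counts over drawn splits were set before.

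Further gene groups were tested and not described above. Of the unfolded protein response chaperones in DMSO, 2 of the 18 tested rose, 7 fell and 9 did not pass (2 up and 8 down adjusted over the list alone) with ASAP1 siRNA (camera adjusted p = 0.013, and adjusted p = 0.475 with an estimated correlation), with CALR, which encodes calreticulin, at -0.91. In trametinib, 1 of the 18 tested rose, 3 fell and 14 did not pass (1 up and 6 down adjusted over the list alone) (camera adjusted p = 0.045, and adjusted p = 0.511 with an estimated correlation), and the call was lost after quantile normalization and after scaling by median ratios (adjusted p = 0.139 and 0.0519). With trametinib under control siRNA, 0 of the 18 tested rose, 10 fell and 8 did not pass (0 up and 11 down adjusted over the list alone) (camera adjusted p = 0.00408, and adjusted p = 0.373 with an estimated correlation), and with ASAP1 siRNA 0 of the 18 tested rose, 10 fell and 8 did not pass (0 up and 13 down adjusted over the list alone) (camera adjusted p = 0.00835, and adjusted p = 0.465 with an estimated correlation). For receptor tyrosine kinase genes with ASAP1 siRNA in DMSO, 0 of the 9 tested rose, 2 fell and 7 did not pass (1 up and 2 down adjusted over the list alone), including ERBB3 (-1.07) and FGFR4 (-0.96; camera adjusted p = 0.0454, and adjusted p = 0.346 with an estimated correlation), and the call was lost after either scaling (adjusted p = 0.0759 and 0.0675). For NF-kB and inflammatory genes with ASAP1 siRNA in DMSO, 3 of the 7 tested rose, 0 fell and 4 did not pass (4 up and 0 down adjusted over the list alone) (camera adjusted p = 0.00873, and adjusted p = 0.373 with an estimated correlation), and by single siRNA 7 of 7 rose with ASAP1 si4 (median 0.68) while 2 rose and 1 fell with ASAP1 si17 (0.041). Among oxidative phosphorylation genes with trametinib under control siRNA, 13 of the 33 tested rose, 1 fell and 19 did not pass (13 up and 1 down adjusted over the list alone) (camera adjusted p = 0.000395, and adjusted p = 0.373 with an estimated correlation). Between ASAP1 and control siRNA in trametinib, 1 of the 33 tested rose, 7 fell and 25 did not pass (1 up and 9 down adjusted over the list alone) (camera adjusted p = 0.00422, and adjusted p = 0.511 with an estimated correlation), and by single siRNA 3 rose and 19 fell with ASAP1 si4 (median -0.16) while 4 rose and 3 fell with ASAP1 si17 (-0.014).

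Of the adhesion and actin partners of ASAP1 with trametinib under control siRNA, 2 of the 28 tested rose, 14 fell and 12 did not pass (3 up and 14 down adjusted over the list alone) (camera adjusted p = 0.00724, and adjusted p = 0.373 with an estimated correlation), among them TPM4 (-1.14) and FSCN1 (-1.01). Between ASAP1 and control siRNA in trametinib, 8 of the 28 tested rose, 1 fell and 19 did not pass (8 up and 1 down adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0967, and adjusted p = 0.511 with an estimated correlation). SRF-MRTF target genes had 8 decreases of 13 with trametinib under control siRNA and 1 increase, with 4 not past the test and 8 and 3 adjusted over the list alone (camera adjusted p = 0.00934, and adjusted p = 0.373 with an estimated correlation). Extracellular matrix genes went both ways with ASAP1 siRNA in DMSO: 8 of the 28 tested rose, 3 fell and 17 did not pass (9 up and 5 down adjusted over the list alone) (camera adjusted p = 0.17, and adjusted p = 0.59 with an estimated correlation), MMP14 (0.91) being higher and BGN (-0.83) lower. Cell-cycle inhibitors, p53 targets, ARF GTPase genes, housekeeping genes and histone genes did not pass in DMSO between ASAP1 and control siRNA (adjusted p = 0.532, 0.824, 0.986, 0.979 and 0.072).

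The count of genes between ASAP1 and control siRNAs was weighed against differences between single siRNAs. Grouping ASAP1 si4 with control si4 against ASAP1 si17 with control si5, which mixes the kinds, called 2147 genes in DMSO and 2389 in trametinib, more than the 1400 and 1733 of the real grouping. Genes changed the same way in all 4 pairs numbered 307 and 344 in the real grouping against 633 and 692 in that mixed one. Differences between single siRNAs unrelated to ASAP1 could therefore account for counts of this size. Loss of ASAP1 stays open, as 4 siRNAs allow only 3 groupings, and the counts do not show which genes follow from it.

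The lower muscle list was weighed against an effect of 1 ASAP1 siRNA alone, which is argued against in trametinib, where the highest median among the 4 pairs was -0.53 and the controls differed by -0.083. In DMSO it stays open, since the highest median, -0.36, lay within the difference between the control siRNAs (-0.41), a condition added to this test after its outcome was seen. Differences between single siRNAs stay open in DMSO by the same value, and in trametinib they cannot be excluded with only 3 groupings of the siRNAs. A lower level of muscle genes with less ASAP1 may be the cause in both treatments and was not separated from these.

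Chance in how these libraries are divided was tested on the counts by other splits of them. The labels do not say whether the libraries come from separate cultures, so chance differences between cultures are not excluded by such splits. A chance division of these libraries can be excluded for the counts between siRNAs of 1 kind. Between control siRNAs 1 of 35 splits, the real one, gave as many as 2563 in DMSO (highest other 351) and 2469 in trametinib (932). Between ASAP1 siRNAs 1 of 35 gave as many as 3868 (837) and 4172 (799). A chance division can also be excluded for trametinib, where 1 of 100 drawn splits gave as many as 2380 with control siRNA (1004) and 2 of 100 as many as 2519 with ASAP1 siRNA. The other of these, with 2728, set 7 libraries of ASAP1 si4 and 1 of ASAP1 si17 against the reverse, so it followed the siRNA. With treatments exchanged within each siRNA and 8 means in the fit, 1 of 100 splits gave as many as 3921 with control siRNA (1884) and 1 of 100 as many as 4089 with ASAP1 siRNA (3091).

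For comparisons between kinds of siRNA, 1 of 100 drawn splits gave as many as 1400 and 1733 between ASAP1 and control siRNA in DMSO and trametinib (374 and 1044) and 14 for the interaction (0). The same held for ASAP1 si4 against the controls, at 4030 and 4198 (2491 and 2059), and for ASAP1 si17, at 2420 and 2718 (880 and 2603). These drawn splits do not decide, since they part libraries of the same siRNA, which the real groups keep together. Groupings that keep them together number 3 for each such comparison, too few for a share under 0.05. The highest other was 2147 against 1400 and 2389 against 1733 for ASAP1 siRNA in DMSO and trametinib, and 2942 against 2420 and 2931 against 2718 for ASAP1 si17 against the controls. It was 3187 against 4030 and 3256 against 4198 for ASAP1 si4 and 2 against 14 for the interaction.

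Libraries with the same siRNA, treatment and set letter differed from each other. On the first component of the residuals, with 35.5% of their variance, the libraries of 16 of 16 such pairs lay on opposite sides, and the one with the higher score had more reads in 8 of 16. For 32 of 32 libraries, the closest library of the same siRNA and treatment carried the other set letter. MYH3 differed within these pairs by a median ratio of 2.82 (1.2 to 13.7), MYOG by 2.21 (1.01 to 3.83), MKI67 by 1.45 (1.06 to 11) and ASAP1 by 1.18 (1.01 to 1.9). These genes were chosen after their values were seen. Only the library number in the title separates the libraries of such a pair, and the labels do not say what it stands for. MYOG was higher in the library with the lower number in all pairs except ASAP1 si4 with DMSO in set A (1.82 against 2.79 FPKM). Library numbers were not used to pair libraries. The difference within pairs was therefore not taken out in any fit and counts as spread. Whether the treatment of 2 or 3 days is behind it could not be tested, since the labels do not assign either duration to a library.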
